A study of Mus musculus with 8 samples.

How the data were processed

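The series profiled open chromatin by ATAC-seq, an assay in which the Tn5 transposase cuts and tags accessible DNA, in satellite cells, the resident stem cells of skeletal muscle, from C57BL/6 mice. It comprised 8 libraries in 4 groups of 2. The groups, per the labels, were freshly isolated cells (QSC), cells isolated 2.5 days after muscle injury (ASC), cells cultured towards differentiation with a control siRNA, and cells cultured the same way with an siRNA against LncMyod, a long noncoding RNA expressed from the neighbourhood of the gene for the myogenic transcription factor MyoD. The LncMyod siRNA was applied for 48 h before harvest, per the labels' protocols. No such time was recorded here for the control siRNA. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

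A list of broad peaks per library was used, called on each library by itself and not on pooled replicates. Per the submitters' processing notes, the tools were bcl2fastq 2.19, Trimmomatic 0.36, Bowtie2 2.3.2, Picard 2.9.2, SAMtools 1.3, MACS2 2.1.1 and bedtools 2.26.0, and the build was mm10. Their settings, and whether read ends were shifted for the transposase, are not given in the sources used here. Each deposited peak carries a fold enrichment over the local background of its own library, as the authors' peak caller gave it. It also carries a deposited −log10 p and −log10 q, and a display score that equals the −log10 q times a constant with a ceiling. The lowest −log10 q of a library lay between 1.00 and 1.01, no peak was narrower than 200 bp, and no gap between neighbouring peaks was under 801 bp. Between 51 and 62 peak numbers per library were missing from the numbering, so some peaks had been removed by a filter whose rule is not given in the sources used here. Fold, −log10 p and −log10 q are the authors' values and were used only to describe, rank or filter peaks within a library.

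The lists carry no read counts, so the sequencing depth of each library is unknown, and no counting interval is given. A deeper library can yield more and wider peaks, and a locus without a peak is not shown to be closed. Libraries held between 59666 and 95449 peaks covering 42.4 to 64 Mb. For that reason covered length was scaled to the total covered length of each library, and results were repeated with lists of equal length.

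Peaks of all libraries on chromosomes 1 to 19, X and Y were merged where they overlapped, giving 141301 regions with a median width of 648 bp. The merging was computed with numpy. A library held a region when any of its peaks overlapped it by at least 1 bp. A region was specific to a group of a pair when both of its replicates held it and neither replicate of the other group did. With 2 libraries against 2, an exact permutation test has 3 splits and cannot give a p under 0.333, so these counts have no p and stand beside the counts from the 2 other splits of the same 4 libraries. Similarity was the Jaccard index, the base pairs covered in both of a pair of libraries over those covered in either, and was tested by an exact one-sided permutation over all ways to pair the 8 libraries.

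For each gene the length covered by peaks was summed over its locus, defined as the gene body with 10 kb on both sides, and analysed as log2(scaled bp + 500 bp). Fold changes are on that scale and understate the change of loci with little covered length. Gene positions came from the RefSeq table of GRCm38.p6, whose primary chromosomes have the coordinates of mm10. Of 34328 protein-coding and long noncoding RNA genes on chromosomes 1 to 19 and X, 27938 had at least 200 covered bp in at least 2 libraries and were tested. Loci of neighbouring genes can share peaks and are not independent. limma 3.58.1 fitted the 4 group means to all 8 libraries together, with a trended prior, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. "Rose" and "fell" below refer to covered length past that threshold.

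A total of 13 gene lists with 326 entries, all matched to the table, was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. No gene stood in more than 1 list. The lists were genes known from quiescent satellite cells, Notch pathway genes, immediate early and dissociation stress genes, cell cycle genes, the myogenic program (transcription factors, fusion and synapse genes), contractile genes (sarcomere and excitation-contraction coupling), Wnt, BMP and TGF-beta genes, and markers of fibroadipogenic, endothelial, leukocyte, glial and mural cells and of hepatocytes, a cell type with no part in muscle. How many of the marker genes satellite cells themselves express was not assessed.

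The named genes followed a fixed rule. It took up to 8 protein-coding genes per direction past the threshold in order of p, whose replicates did not overlap between groups. It also took up to 4 members per list with the most specific regions, the 5 specific regions per direction with the highest lower replicate fold, and Pax7, Myf5, Myod1, Myog, Mymk, Spry1, Calcr and the LncMyod locus in every comparison. Further list members that are named were chosen after their values were seen, as examples of members past the threshold or closest to it. Some genes that the rule or a list would name are not reported here. The gene table holds no gene called LncMyod, so the 35 kb upstream of Myod1 are reported in its place. The siRNA acts on RNA, which this assay does not measure, so the knockdown itself could not be checked here.

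The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternative settings were a −log10 q of at least 5, lists shortened to the 59666 peaks with the highest −log10 p, a 50% overlap, 500 bp bins, merging across 100 bp, regions merged from a pair's libraries only, other similarity indices, no scaling, quantile normalization, pseudocounts of 100 and 2000 bp, no filter, peak number in place of covered length, a fit on a pair's libraries only, the replicate number as a block, and leaving out each library in turn. In the last, a lone library of a group is assumed to vary like the others. Chosen after seeing the data were gene bodies alone, gene bodies with 50 kb, gene ends within 500 bp, the 20000 strongest peaks, and a background matched on −log10 p.

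The planned share of regions at transcription start sites was replaced by the share within 1 kb of either end of a gene, because the gene table gives no strand. Loci around start sites and motif content were not run, since neither strand nor genome sequence was used here. On simulated data with 200 of the 27938 genes changed, a log2 change of 1 was recovered in 46% of genes for ASC against QSC, 49% for control siRNA against ASC and 44% for LncMyod siRNA against control siRNA, and a change of 2 in 95%, 94% and 93%. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.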

Results

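Accessible chromatin was mapped in 8 libraries of mouse satellite cells, with 2 libraries in each of 4 groups: freshly isolated cells (QSC), cells isolated 2.5 days after injury (ASC), cells cultured towards differentiation with control siRNA, and cells cultured the same way with LncMyod siRNA. The QSC libraries held 69595 and 64991 peaks, the ASC libraries 70341 and 59666, the control siRNA libraries 82854 and 81327, and the LncMyod siRNA libraries 95449 and 79396. Peaks covered 50.7 and 47.1 Mb in QSC, 51.2 and 42.4 Mb in ASC, 52.4 and 52.3 Mb in control siRNA, and 64 and 49.7 Mb in LncMyod siRNA. Peak strength varied, and the share of peaks with a −log10 q of at least 5 ran from 50.3% in LncMyod siRNA replicate 2 to 69.9% in control siRNA replicate 1. Of the 141301 merged regions, 35293 were held by all 8 libraries.

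Libraries of the same group shared more covered sequence than libraries of different groups. The Jaccard index averaged 0.625 over the 4 replicate pairs and 0.479 over the 24 other pairs, a difference of 0.147 (exact one-sided permutation p = 0.00952, the real pairing giving the largest value of all). The replicate index was 0.694 in QSC, 0.692 in control siRNA, 0.592 in ASC and 0.523 in LncMyod siRNA. The LncMyod siRNA pair was an exception to the general order. Its replicate 1 had an index of 0.630 and 0.625 with the control siRNA libraries, and its replicate 2 an index of 0.559 and 0.561, all above the 0.523 between the replicates themselves. For replicate 2 this order turned among the 20000 strongest peaks (0.721 and 0.716 against 0.726) and with the overlap coefficient (0.737 and 0.737 against 0.785).

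**Figure D1:**
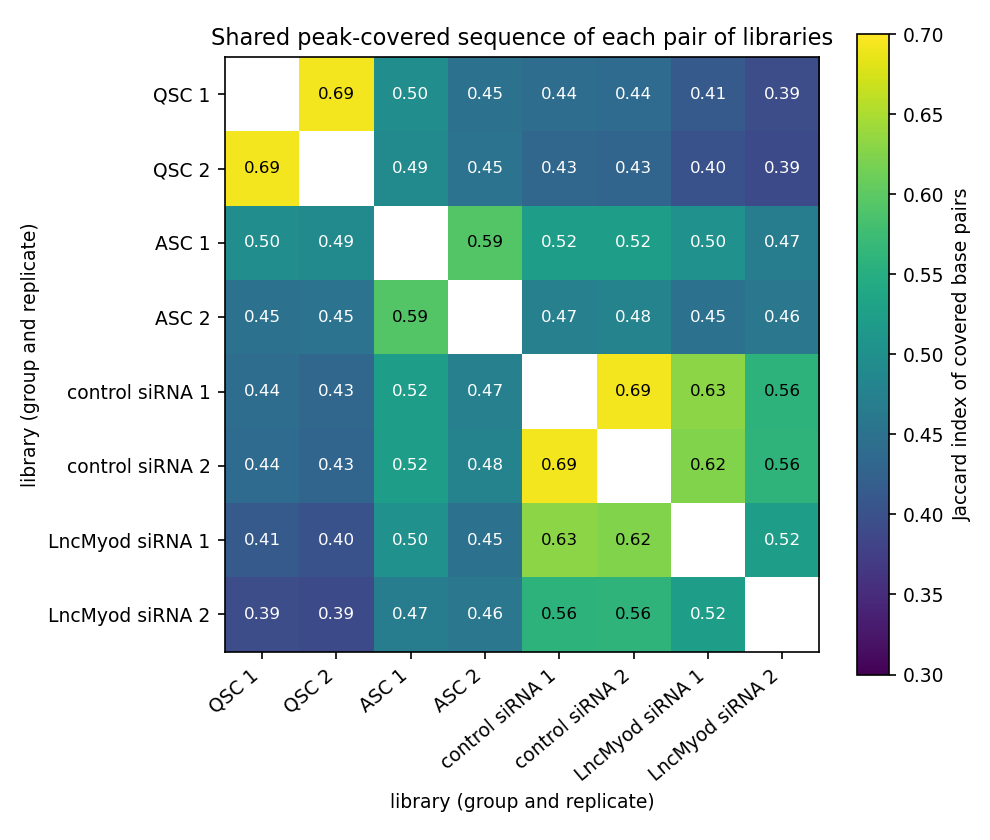
Jaccard index of peak-covered base pairs for every pair of the 8 libraries, with libraries on both axes and the index printed in each cell. Replicate pairs reach 0.694 in QSC and 0.692 in control siRNA, while the LncMyod siRNA pair, at 0.523, lies below the values of its members with control siRNA.

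The comparison of ASC with QSC asked how chromatin accessibility differs after injury has activated satellite cells. As a list, loci of genes known from quiescent satellite cells had less covered length in ASC (adjusted p = 0.0191 by camera; adjusted p = 0.249 with an estimated correlation), and 7 of 30 fell. They included Cd34, a surface glycoprotein of quiescent satellite cells, which fell from 5.03 ± 0.401 to 1.88 ± 0.808 kb (SD, n = 2), and Calcr, the calcitonin receptor, which fell from 4.17 ± 0.0485 to 2.02 ± 0.278 kb (SD, n = 2). Leukocyte markers had more as a list (adjusted p = 0.0370; adjusted p = 0.249 with an estimated correlation), and 6 of 22 rose, among them Runx3, a Runt-family transcription factor, from 2.71 ± 0.474 to 5.04 ± 0.279 kb (SD, n = 2). Cell cycle genes that rose included Ccnd2, encoding cyclin D2, and Plk1, a mitotic kinase. More regions were specific to QSC (12069) than to ASC (8465), and 39371 were held by all 4 libraries.

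Of the 30 quiescence genes, 7 fell, 1 rose and 22 did not pass the threshold; adjusted over the list alone, 8 fell and 1 rose. The list had a median log2 change of −0.17. Besides Cd34 (log2 change −1.26, SE 0.24, adjusted p = 0.0184) and Calcr (−0.89, SE 0.17, adjusted p = 0.0202), the genes that fell were Chodl, Foxo1, Nfia, Tcf4 and Tenm3. The gene that rose was Ebf1, a transcription factor best known from B cells and mesenchymal cells, with 6.46 ± 1.07 kb in ASC against 2.99 ± 0.147 kb in QSC (SD, n = 2). The list's loci held 79 QSC-specific and 18 ASC-specific regions. Nfia, a nuclear factor I transcription factor, had 16 QSC-specific regions against 2 ASC-specific, and the teneurin gene Tenm4 had 14 against 3. The transcription factor gene Tcf4 had 13 against 1, and Tenm3 had 9 against 3. The list's call was lost with quantile normalization, the stricter peak threshold, equal list lengths and gene bodies alone. Its adjusted p was 0.0544 without QSC replicate 1 and 0.104 without ASC replicate 1.

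Of the 22 leukocyte markers tested, 6 rose, none fell and 16 did not pass, counts that were the same adjusted over the list alone, and the median log2 change was 0.25. They were Cd3e, a T cell receptor subunit, Runx3 (log2 change 0.80, SE 0.13, adjusted p = 0.0115), the complement gene C1qa, and the leukocyte genes Laptm5, Itgam and Ptprc, for which both QSC libraries were listed at 0. The ASC libraries had little there: 958.6 and 1116.3 scaled bp at Laptm5, 532.8 and 297.2 at Itgam, and 769.7 and 286.3 at Ptprc. The summed covered length of the 22 loci was 26.3 ± 0.962 kb in QSC, 37.4 ± 0.170 kb in ASC, 46.7 ± 0.375 kb in control siRNA and 46.3 ± 6.55 kb in LncMyod siRNA (SD, n = 2 each). The call was lost with quantile normalization, a 2000 bp pseudocount, peak number, the stricter threshold, equal list lengths and gene bodies alone. Its adjusted p was 0.0858 without QSC replicate 1 and 0.240 without ASC replicate 1. The Ptprc value turned to a log2 change of −0.087 with 50 kb on both sides of the gene.

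None of the other 11 lists passed. Among cell cycle genes, 3 of 33 rose and none fell (adjusted p = 0.468): Ccnd2 had 3.82 ± 0.161 kb in ASC and 2.29 ± 0.0556 kb in QSC, Plk1 had 2.45 ± 0.392 and 0.967 ± 0.182 kb, and the helicase gene Mcm5 had 3.53 ± 0.252 and 1.82 ± 0.484 kb (SD, n = 2 each). In the myogenic program, Mef2c, Smyd1 and Tead4 rose and Musk, the muscle-specific kinase of the neuromuscular junction, fell (4 of 31, adjusted p = 0.468). Contractile genes moved both ways (7 of 49 rose, 2 fell, adjusted p = 0.955). Casq2, encoding a calcium-binding protein of the sarcoplasmic reticulum, rose from 0.628 ± 0.0980 to 4.55 ± 0.568 kb and Trdn, encoding triadin, fell from 2.92 ± 0.136 to 0.491 ± 0.669 kb (SD, n = 2). Notch genes Maml2 and Heyl fell and Lfng rose (3 of 18, adjusted p = 0.891). Immediate early genes Jun and Klf2 rose and Hspa1a and Egr1 fell (4 of 29, adjusted p = 0.810). Egr1 had a log2 change of 0.052 over the gene body alone.

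Adjusted p was 0.862 for Wnt, BMP and TGF-beta genes (1 of 28 rose), 0.817 for fibroadipogenic markers (2 of 20 rose, 1 fell), 0.817 for endothelial markers (2 of 19 rose, 2 fell), 0.229 for glial markers (S100b and Mbp rose of 10 tested), 0.401 for mural markers (1 of 14 rose, 2 fell) and 0.587 for hepatocyte genes (1 of 16 tested fell). Adjusted over the list alone, the genes that rose and fell numbered 3 and 0 for the cell cycle, 3 and 2 for the myogenic program, 7 and 3 for contractile genes, 1 and 2 for Notch, 3 and 3 for immediate early genes, 4 and 2 for the Wnt, BMP and TGF-beta list, and 3 and 1 for fibroadipogenic, 2 and 2 for endothelial, 4 and 0 for glial, 1 and 4 for mural and 0 and 1 for hepatocyte genes. The median and the test had opposite signs for the Notch, immediate early and mural lists, and for the immediate early, fibroadipogenic and Wnt, BMP and TGF-beta lists the mean was above 0 while the test pointed down.

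Across all tested genes, 2112 loci had more and 1468 less covered length in ASC; with quantile normalization the split was 1617 and 1726. The strongest protein-coding gain was at Oas3, an interferon-induced oligoadenylate synthetase gene (chromosome 5, 120753098–120777684), with 2.92 ± 0.197 kb in ASC (SD, n = 2) and no peak in either QSC library (adjusted p = 0.00187). Bmerb1, the melanocortin receptor gene Mc3r, the gliomedin gene Gldn, Ifitm7, the urotensin gene Uts2 and Galnt13 were likewise listed at 0 in QSC, and the Bmerb1 and Ifitm7 loci overlap. Clip4 (chromosome 17, 71769674–71864210) rose from 0.790 ± 0.0805 to 4.17 ± 0.171 kb. Genes listed at 0 in ASC were Nat8f2, the alcohol dehydrogenase gene Adh1 and the transporter gene Slc22a22. Kcnt2, encoding a sodium-activated potassium channel (chromosome 1, 140245657–140614045), fell from 6.28 ± 0.181 to 1.11 ± 0.160 kb (log2 change −2.08, SE 0.14, adjusted p = 0.00187) and held 8 QSC-specific regions. The calcium-activated potassium channel gene Kcnma1 fell from 24.2 ± 0.0725 to 12.4 ± 0.412 kb and held 13. Svep1, Prex2 and Mpp7 fell with 6 QSC-specific regions each.

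The lineage genes Pax7 and Myf5, transcription factors of satellite cells and myoblasts, had log2 changes of 0.01 (adjusted p = 0.999) and −0.05 (adjusted p = 0.926). Myod1 had 3.29 ± 0.397 kb in ASC and 2.12 ± 0.131 kb in QSC (SD, n = 2; log2 change 0.53, SE 0.16, adjusted p = 0.0722). Myog, the myogenin gene, had a log2 change of 0.35 (adjusted p = 0.320), the fusion gene Mymk 0.07 (adjusted p = 0.959) and Spry1, a receptor tyrosine kinase inhibitor, −0.13 (adjusted p = 0.650). The strongest ASC-specific regions lay inside Tenm3 (chromosome 8, 49043098–49043872) and Gpc6 (chromosome 14, 117527075–117527578), the first with fold enrichments of 8.16 and 8.37 in the deposited lists. The strongest QSC-specific region (chromosome 3, 58245207–58245843, folds 10.4 and 10.6) lay 31835 bp from the nearest gene, Gm40057, and the next inside Cabcoco1 (chromosome 10, 68472652–68473184). Gene ends were within 1 kb of 11.7% of ASC-specific and 7.19% of QSC-specific regions, against 37.9% of the regions held by all 4 libraries, which were wider (median 1112 bp, against 692 and 590 bp).

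The other splits of these 4 libraries gave 1647 and 1023 specific regions in all, against 20534. The excess of QSC-specific regions turned to 17931 for ASC against 12960 for QSC without ASC replicate 2, and the ASC count was 14368 and the QSC count 18433 without ASC replicate 1, when a single library stands for the group. With the stricter threshold the ASC count was 5201. The number of changed genes was 926 without QSC replicate 1, 712 without QSC replicate 2 and 1655 without ASC replicate 2. It was 1820 without scaling, 1186 in a fit on these 4 libraries and 7086 with 50 kb on both sides of the gene.

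**Figure D2:**
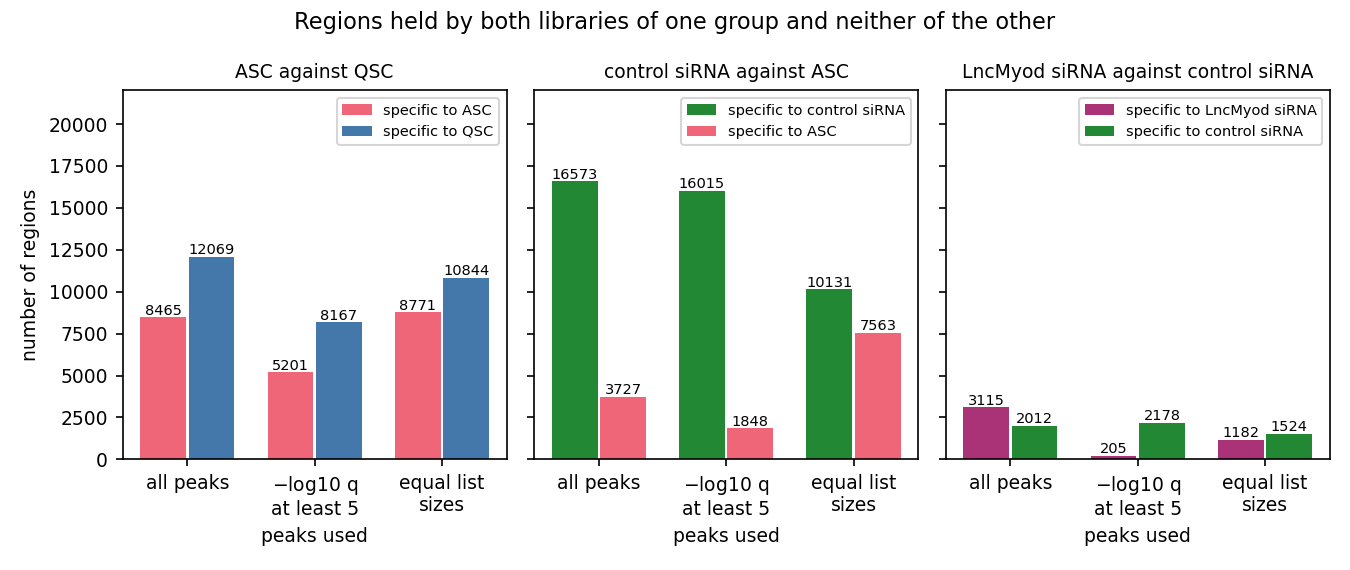
Number of regions specific to each group of a comparison, meaning held by both of its replicates and by neither of the other group, with all peaks, with −log10 q of at least 5 and with equal list lengths. Control siRNA-specific regions outnumber ASC-specific ones under each of these settings (16573 against 3727 with all peaks), while the order for LncMyod siRNA and control siRNA changes from 3115 against 2012 to 205 against 2178.

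The comparison of control siRNA with ASC asked what differs in cells cultured towards differentiation. ASC were isolated after muscle injury, whereas control siRNA cells were cultured with an siRNA. Injury, culture, siRNA treatment and differentiation therefore cannot be told apart here. As a list, contractile genes had more covered length in control siRNA (adjusted p = 7.32e-12 by camera; adjusted p = 0.136 with an estimated correlation), and 10 of 49 rose. Tnnt3, encoding fast skeletal troponin T, rose from 0.899 ± 0.336 to 5.40 ± 1.52 kb, Neb, encoding the thin-filament protein nebulin, from 2.13 ± 0.297 to 5.40 ± 0.0438 kb, and Acta1, encoding skeletal alpha-actin, from 2.21 ± 0.138 to 4.11 ± 0.238 kb (SD, n = 2 each). Immediate early genes had less as a list (adjusted p = 0.0172; adjusted p = 0.350 with an estimated correlation), with 1 of 29 past the threshold, Fosb, an AP-1 subunit gene, which fell from 6.18 ± 0.966 to 3.28 ± 0.161 kb. Many more regions were specific to control siRNA (16573) than to ASC (3727), and 45000 were held by all 4 libraries.

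Of the 49 contractile genes, 10 rose, none fell and 39 did not pass, with 24 rising and none falling adjusted over the list alone. The log2 change was positive in 42 genes with a median of 0.60. The genes that rose were Klhl41, Tnnt3 (log2 change 2.07, SE 0.27, adjusted p = 0.0187), Actc1, Acta1 (0.77, adjusted p = 0.0257), Xirp2, Neb (1.17, SE 0.22, adjusted p = 0.0388), Myom2, Tcap, Tpm2 and Trdn. Their loci and those of the other members held 91 control siRNA-specific regions against 10 ASC-specific. Ttn, encoding the giant sarcomere protein titin (chromosome 2, 76703980–76982557), held 11 of the former and none of the latter, with 14.8 ± 1.38 kb in control siRNA and 3.37 ± 0.291 kb in ASC (SD, n = 2; log2 change 1.98, SE 0.47, adjusted p = 0.0649). The junctophilin genes Jph1 and Jph2 held 6 and 5. The summed covered length of the list was 141.0 ± 3.82 kb in QSC, 154.7 ± 3.18 kb in ASC, 238.4 ± 4.24 kb in control siRNA and 200.4 ± 25.7 kb in LncMyod siRNA (SD, n = 2 each).

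**Figure D3:**
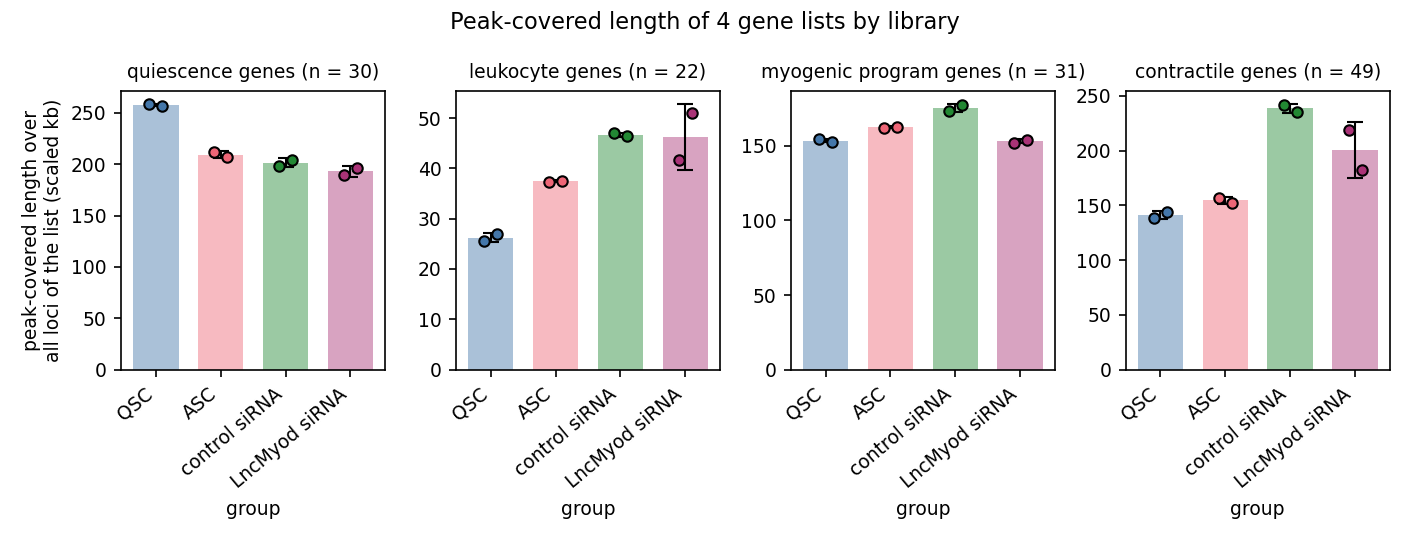
Scaled covered length in kb summed over the loci of 4 gene lists in each of the 4 groups, with bars for means, error bars for the SD and points for the 2 libraries. The contractile list reaches 238.4 kb in control siRNA against 154.7 kb in ASC, and its LncMyod siRNA libraries lie apart, with an SD of 25.7 kb.

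Immediate early and dissociation stress genes had a median log2 change of −0.19. The change was negative in 26 of 29 genes, and Fosb (−0.81, SE 0.13, adjusted p = 0.0272) was the gene that fell, also adjusted over the list alone, with 28 not past the threshold. The call was lost without scaling and with quantile normalization, peak number, equal list lengths, gene bodies alone and gene bodies with 50 kb. Its adjusted p was 0.0960 without ASC replicate 2. Leukocyte markers were higher as a list (adjusted p = 0.0172; adjusted p = 0.220 with an estimated correlation), with a median log2 change of 0.01 and a mean of 0.37. Of these, 4 rose and 18 did not pass, and 5 rose adjusted over the list alone. Runx3 had a log2 change of 0.66 (adjusted p = 0.0401) and the integrin gene Itgam 0.99 (adjusted p = 0.0493), while the complement genes C1qb and C1qc were listed at 0 in ASC and share their peaks. The leukocyte call was lost with peak number, equal list lengths and 50 kb on both sides, and its adjusted p was 0.0960 without ASC replicate 2.

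No other list passed. In the myogenic program none of 31 genes passed, with 2 rising adjusted over the list alone, and adjusted p = 0.148 became 0.0377 without scaling. Megf10, Mef2a, Mef2c and Tead4 held 5, 4, 4 and 4 control siRNA-specific regions. Myog had 5.23 ± 0.561 kb in control siRNA and 2.58 ± 0.262 kb in ASC (SD, n = 2; log2 change 0.90, SE 0.20, adjusted p = 0.0584), and Mymk 6.55 ± 0.512 and 3.16 ± 1.3 kb (0.99, SE 0.36, adjusted p = 0.167). Adjusted p was 0.496 for quiescence genes, 0.839 for Notch genes (Maml2 rose), 0.312 for cell cycle genes (Mcm5 fell), 0.496 for Wnt, BMP and TGF-beta genes (Bmp4 fell), 0.148 for glial markers, 0.131 for mural markers, 0.927 for endothelial markers, 0.399 for hepatocyte genes (Ttr rose) and 0.376 for fibroadipogenic markers, the last 0.0242 without ASC replicate 2. Adjusted over the list alone, the counts of rising and falling genes were 0 and 0 for quiescence and endothelial genes, 1 and 1 for Notch, 0 and 1 for cell cycle, Wnt, BMP and TGF-beta, glial and fibroadipogenic genes, and 1 and 0 for mural and hepatocyte genes.

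Across all tested genes, 636 loci had more and 480 less covered length in control siRNA; without scaling the split was 283 and 85. The median change over all genes was −0.08 with scaling and 0.04 without. Cmah, a sialic acid hydroxylase gene (chromosome 13, 24327404–24477289), rose from 0.159 ± 0.0298 to 4.90 ± 0.292 kb (SD, n = 2; adjusted p = 0.00892) with 9 control siRNA-specific regions. Cpne4, encoding a calcium-binding copine (chromosome 9, 104566701–105034544), rose from 0.349 ± 0.0102 to 4.70 ± 1.06 kb with 8, and the receptor tyrosine phosphatase gene Ptprt from 1.84 ± 0.00233 to 6.22 ± 0.863 kb with 9. Ly6f, Gm11213, Tmem156 and Prl7c1 were listed at 0 in ASC, and Gm11213 had a log2 change of −0.58 with 50 kb on both sides. Ddr2, encoding a collagen receptor kinase (chromosome 1, 169972307–170110836), fell from 13.4 ± 0.0424 to 7.16 ± 0.0686 kb (log2 change −0.86, SE 0.08, adjusted p = 0.0139). The protocadherin gene Pcdh10, the calcium pump gene Atp2b1, Ddx43, the protein kinase C gene Prkcb and Zkscan16 also fell, and Capn6 and Lrat were listed at 0 in control siRNA.

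Pax7 had a log2 change of −0.25 (adjusted p = 0.349), Myf5 −0.50 (adjusted p = 0.171), Myod1 0.05 (adjusted p = 0.866), Calcr 0.31 (adjusted p = 0.344) and Spry1 0.09 (adjusted p = 0.758). The strongest control siRNA-specific region (chromosome 18, 58725524–58725905, folds 12.3 and 12.6) lay 45953 bp from Isoc1, and the next (chromosome 3, 61097053–61097487) 88070 bp from P2ry1. The strongest ASC-specific region lay inside Zc3hav1, an antiviral zinc finger gene (chromosome 6, 38315952–38316438). Gene ends were within 1 kb of 8.48% of control siRNA-specific and 12.3% of ASC-specific regions, against 34.6% of those held by all 4 libraries, with median widths of 514, 635 and 1073 bp.

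The other splits gave 1935 and 1760 specific regions, against 20300. The ratio of control siRNA-specific to ASC-specific regions was 4.45 with all peaks, 8.67 with the stricter threshold (1848 ASC-specific), 1.34 with equal list lengths (10131 against 7563), 2.12 with 500 bp bins (8253 ASC-specific), 2.88 without ASC replicate 1 (8617 ASC-specific) and 1.69 without ASC replicate 2 (10690 ASC-specific). The 1116 changed genes became 707 without ASC replicate 1, 0 without ASC replicate 2 (limma, with 5123 at an unadjusted p under 0.05), 0 without control siRNA replicate 1 (4229) and 1 without control siRNA replicate 2, so at most 1 of the genes called here passed when any of these last 3 libraries was left out. They became 2066 with the stricter threshold, 2979 with equal list lengths, 1757 with 50 kb on both sides and 704 in a fit on these 4 libraries.

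The comparison of LncMyod siRNA with control siRNA asked whether knockdown of the noncoding RNA changes accessibility during culture. Loci of the myogenic program and of contractile genes had, as lists, less covered length in the knockdown with all peaks (adjusted p = 7.24e-04 and 0.00143 by camera). Both calls were lost with an estimated correlation (adjusted p = 0.131 and 0.471) and with equal list lengths (adjusted p = 0.743 and 0.0547), and the myogenic direction turned with the stricter threshold. Tead4, a TEA-domain transcription factor gene of the myogenic program, had 7.24 ± 0.226 kb against 9.48 ± 0.0443 kb, and Ckm, encoding muscle creatine kinase, 2.11 ± 0.200 kb against 3.75 ± 0.0715 kb (SD, n = 2 each). No gene of either list passed the threshold by itself in limma. Over the genome 3115 regions were specific to LncMyod siRNA and 2012 to control siRNA, with 58774 held by all 4 libraries.

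With scaling, the myogenic program had a negative log2 change in LncMyod siRNA in 30 of 31 genes and a median of −0.16. The median change over all genes was −0.05 with scaling and 0.03 without, so the number of negative genes may depend on the scaling. Its members with the lowest p were Tead4 (−0.37, SE 0.09, adjusted p = 0.283) and Dok7, a Musk adaptor gene of the neuromuscular junction (−0.44, SE 0.12, adjusted p = 0.317). Mef2a, Mef2d, Smyd1 and Tead4 held 1 control siRNA-specific region each, and no member held a LncMyod siRNA-specific region. The summed covered length was 153.6 ± 1.20 kb in QSC, 162.7 ± 0.495 kb in ASC, 175.4 ± 2.9 kb in control siRNA and 153.3 ± 1.49 kb in LncMyod siRNA (SD, n = 2 each). The median was 0.04 with the stricter threshold (adjusted p = 0.743) and −0.03 with equal list lengths, and the call was lost without LncMyod siRNA replicate 1 (adjusted p = 0.0621).

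Contractile genes, also with scaling, had a negative change in 40 of 49 genes and a median of −0.22, which was −0.10 with equal list lengths. Actn3, encoding the fast-fibre actinin, had a log2 change of −0.57 (SE 0.15, adjusted p = 0.315), Ckm −0.70 (SE 0.25, adjusted p = 0.415) and Neb −0.53 (SE 0.22, adjusted p = 0.496). Ttn had 13.7 and 4.05 kb in the LncMyod siRNA libraries and 15.8 and 13.8 kb in the control siRNA libraries (log2 change −0.93, SE 0.47, adjusted p = 0.606) and held 3 control siRNA-specific regions, while Mb, the myoglobin gene, held 2. In all, the list's loci held 15 control siRNA-specific and 6 LncMyod siRNA-specific regions. The call was also lost with gene bodies alone (adjusted p = 0.111) and without LncMyod siRNA replicate 2 (adjusted p = 0.333).

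The other lists gave adjusted p = 0.375 for quiescence genes, 0.187 for Notch genes, 0.615 for immediate early, cell cycle and hepatocyte genes, and 0.891 for Wnt, BMP and TGF-beta genes and for fibroadipogenic, endothelial, leukocyte, glial and mural markers. With the stricter threshold immediate early genes were higher (adjusted p = 0.0132) and endothelial markers lower (adjusted p = 0.0333). No member of the 13 lists rose or fell by limma over all genes, of which 2740 had an unadjusted p under 0.05. Adjusted over the list alone, 1 leukocyte marker rose and 1 fell, 1 mural marker rose, and no member of the other lists passed. The median of the mural list was negative and its mean and test positive.

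In all, 6 loci had more covered length in LncMyod siRNA and none had less. Oas1f, another oligoadenylate synthetase gene (chromosome 5, 120847367–120857986), had 1.91 ± 0.105 kb in LncMyod siRNA (SD, n = 2) and was listed at 0 in both control siRNA libraries (adjusted p = 0.0144). Dnah8, encoding an axonemal dynein heavy chain (chromosome 17, 30626935–30875762), rose from 0.680 ± 0.112 to 4.30 ± 0.0592 kb (log2 change 2.03, SE 0.16, adjusted p = 0.0218). Of the 14 regions in its locus, 0 were specific to LncMyod siRNA and 0 to control siRNA. The other 4 were the long noncoding RNA genes Gm14344 and Gm14342, which overlap on chromosome 2, Gm40972 and Gm39714, named after their values were seen. None of the 6 was among the loci called with the stricter threshold, with equal list lengths or with 50 kb on both sides. The count was 38 without scaling, 10 with quantile normalization, 10 with a 2000 bp pseudocount, 23 with equal list lengths and 3 with 50 kb. At these settings all called loci had more covered length. Both directions occurred at other settings. The count was 200 by peak number (160 with more peaks, 40 with fewer), 14 with the stricter threshold (4 more, 10 less) and 50 over gene bodies (41 more, 9 less). It was 0 in a fit on these 4 libraries (2395 at an unadjusted p under 0.05) and without either control siRNA library (1867 and 1951), 343 without LncMyod siRNA replicate 1, and 102 more and 3 less without LncMyod siRNA replicate 2.

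Pax7 had a log2 change of −0.19 (adjusted p = 0.742), Myf5 −0.14 (adjusted p = 0.879), Myod1 −0.07 (adjusted p = 0.930), Myog −0.11 (adjusted p = 0.915), Mymk −0.46 (adjusted p = 0.755), Spry1 −0.37 (adjusted p = 0.494) and Calcr −0.43 (adjusted p = 0.494). In the 35 kb upstream of Myod1 (chromosome 7, 46341474–46376473), each QSC and ASC library had 5 peaks and each cultured library 7. Not scaled to library totals, the covered length there was 4055 and 3887 bp in QSC, 2742 and 3631 bp in ASC, 5051 and 5627 bp in control siRNA, and 5294 and 4666 bp in LncMyod siRNA. LncMyod siRNA replicate 1 also had the largest total covered length, 64 Mb, so no order of the groups can be read from these lengths. Regions at 46370922–46371528, overlapping the noncoding RNA gene Gm45923 and 4945 bp from Myod1, and at 46364193–46364621, 11852 bp from Myod1, were held by all 4 cultured libraries and by none of the QSC and ASC libraries.

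**Figure D4:**
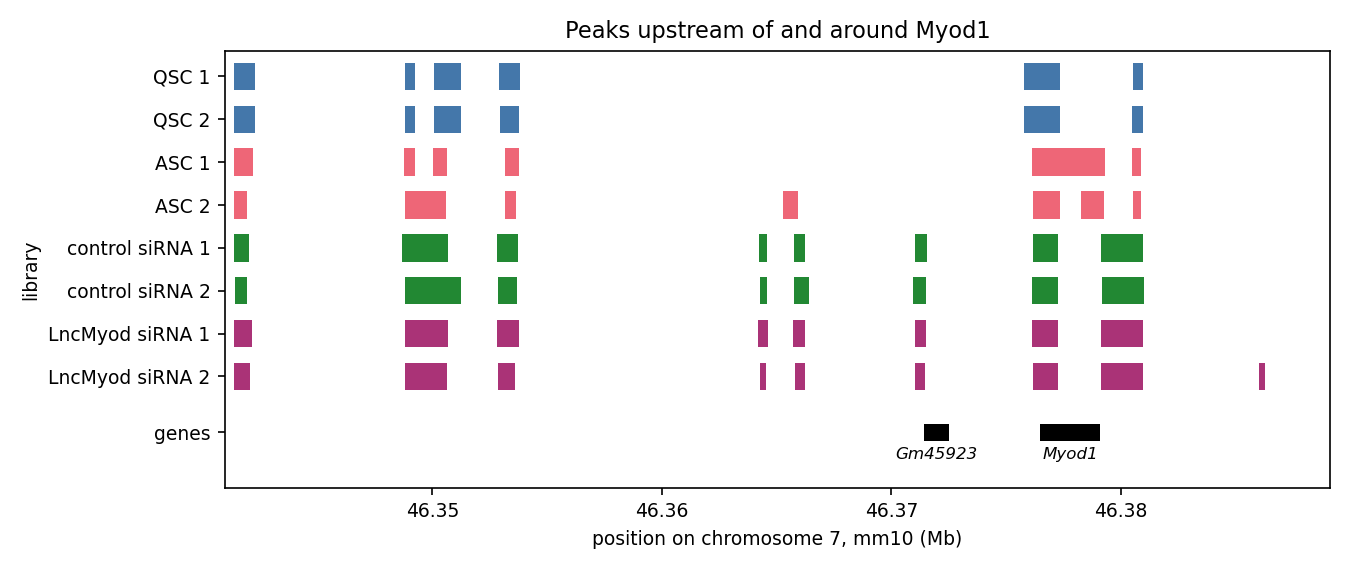
Peaks of each of the 8 libraries along chromosome 7 upstream of Myod1 in mm10 coordinates, with the positions of Gm45923 and Myod1. The 4 cultured libraries share peaks 4945 and 11852 bp from Myod1 that the QSC and ASC libraries lack.

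The strongest LncMyod siRNA-specific region (chromosome X, 4899268–4899496) had folds of 4.35 and 4.71, and the next lay at Gcfc2 and inside Foxp1, a forkhead transcription factor gene (chromosome 6, 99466183–99466738). The strongest control siRNA-specific region lay inside Il1r2, an interleukin-1 decoy receptor gene (chromosome 1, 40115314–40115620, folds 4.86 and 4.88), and the next inside Wscd1. Gene ends were within 1 kb of 14.5% of LncMyod siRNA-specific and 10.2% of control siRNA-specific regions, against 28.5% of those held by all 4 libraries, with median widths of 782, 389 and 971 bp. The other splits of these libraries gave 4383 and 3419 specific regions against 5127, and with the stricter threshold another split (2784) exceeded the real count (2383).

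The order of the counts was reversed with the stricter threshold (205 against 2178), with equal list lengths (1182 against 1524), without control siRNA replicate 1 (4842 against 5796) and without control siRNA replicate 2 (4654 against 6194). It was 14333 against 11970 without LncMyod siRNA replicate 1, 15692 against 2587 without LncMyod siRNA replicate 2, and 3363 were control siRNA-specific with 500 bp bins.

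The regions specific to control siRNA against ASC, called gained in culture here, were then looked up in the knockdown. Of the 16573 control siRNA-specific regions, 9400 (56.7%) were held by both LncMyod siRNA libraries and 1478 (8.92%) by neither, whereas 0.424% of the 45000 regions held by ASC and control siRNA alike were absent from both, or 1.4% with these matched on control −log10 p. These background regions were chosen for presence in 4 libraries and the gained regions for absence from ASC, so a difference between them does not by itself show an effect of the knockdown. The share held by both was 48.4% with the stricter threshold, 65.6% with equal list lengths, and 45% and 43.3% without control siRNA replicate 1 and 2. LncMyod siRNA replicate 2 alone held 58.6% and LncMyod siRNA replicate 1 alone 89.2%. The difference of 8.49 points was 19 without control siRNA replicate 1, 19.8 without control siRNA replicate 2 and 35.9 without LncMyod siRNA replicate 1. Of the LncMyod siRNA-specific regions, 13% were held by both ASC libraries, against 9.49% of the control siRNA-specific regions (odds ratio 1.43), and the other splits of the libraries gave odds ratios of 1.45 and 1.56. The odds ratio was 5.98 with the stricter threshold (0.564 and 1.3 in the other splits) and 4.38 with equal list lengths (0.354 and 0.696). For QSC the shares were 11.3% and 19.1% (odds ratio 0.540, against 1.76 and 1.01 in the other splits), and the odds ratio turned to 1.73 with the stricter threshold and 1.85 with equal list lengths. Across the 27938 genes, which are not independent replicates, the changes LncMyod siRNA against control siRNA and control siRNA against ASC had Pearson's r = −0.31 and Spearman's rho = −0.30. In simulations without any effect, the shared control libraries gave r = −0.50, and the covariance was −0.0498 against a simulated −0.0385. The simulations gave all groups the same spread per gene. The log2 difference between replicates had an SD of 0.324 in control siRNA, against 0.451 in ASC and 0.455 in LncMyod siRNA. The simulated values may therefore be too strong. With the control libraries split so that the 2 changes shared none, r was −0.12 and −0.13 over the same genes. Part of the correlation may therefore come from the shared libraries. Its amount is not settled here, since each change then rested on a single control library. Between the knockdown change and ASC against QSC, which share no library, r was 0.117 and rho 0.106, and r was 0.0684 with equal list lengths and 0.0792 with the stricter threshold.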

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

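Among the tests, gene bodies alone, gene bodies with 50 kb, gene ends within 500 bp, the 20000 strongest peaks and the background matched on −log10 p were chosen after the result was seen. Replicate similarity kept its side of the threshold in all 5 alternatives (exact permutation p = 0.0190 with the stricter peak threshold, 0.00952 in the others). The share of specific regions at gene ends stayed below that of the wider shared regions in all alternatives run. The difference between regions gained in culture and their background in absence from both LncMyod siRNA libraries was 7.52 points with the matched background, 10.6 with the stricter threshold, 9.08 with equal list lengths and 6.59 to 35.9 with 1 library left out. The background was chosen for presence in more libraries than the gained regions, so the sign of this difference tests nothing about the knockdown. Of 663 list values under alternatives, 621 stayed on the same side of the threshold (with the same direction where the list had been called), 37 lost a call, 2 gained one and 3 reversed. Most of the 621 belonged to lists that were not called in the first place. Among the called lists, the call held in 10 of 17 alternatives for quiescence and 8 for leukocyte genes in ASC against QSC. In control siRNA against ASC it held in 9 for immediate early, 16 for contractile and 12 for leukocyte genes. Under LncMyod siRNA it held in 13 for myogenic and 13 for contractile genes. Over all alternatives adjusted p ran from 0.00454 to 0.249 for quiescence and 0.00530 to 0.753 for leukocyte genes in ASC against QSC. It ran from 0.00311 to 0.350 for immediate early, 2.14e-12 to 0.136 for contractile and 0.0128 to 0.427 for leukocyte genes in control siRNA against ASC. Under LncMyod siRNA it ran from 4.38e-04 to 0.743 for myogenic and 2.18e-04 to 0.471 for contractile genes. Of the named genes past the threshold, values under alternatives kept direction and call in 405 of 553 for ASC against QSC, 228 of 348 for control siRNA against ASC and 16 of 29 for LncMyod siRNA against control siRNA. In 146, 119 and 13 the direction was kept and the call lost. The rest reversed: Egr1 in ASC against QSC was 0.052 over the gene body, and with 50 kb Ptprc was −0.087 in ASC against QSC and Gm11213 was −0.58 in control siRNA against ASC. Depth is unknown, so a locus without a peak may be one too shallowly sequenced to be called. Counts of specific regions may mix accessibility with depth, which could not be measured here. With equal list lengths the control siRNA-specific to ASC-specific ratio was 1.34 and the LncMyod siRNA-specific to control siRNA-specific ratio 0.776. Loci of 25 kb around start sites, start sites within 500 bp, and all motif alternatives were not run, for want of strand and sequence. Leaving out a library raises region counts by construction, since a lone library then stands for its group. A fit on fewer libraries has fewer degrees of freedom. For the other changes below the cause was not tested.

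With the stricter threshold the ASC-specific regions numbered 5201 against QSC and 1848 against control siRNA, where the ratio was 8.67. LncMyod siRNA-specific regions numbered 205 and their ratio to control siRNA-specific regions reversed to 0.0941. Changed genes numbered 2066 for control siRNA against ASC, 442 of them among the 1116 called with all peaks, and 14 for LncMyod siRNA, none of them among the 6. The adjusted p was 0.245 for quiescence and 0.753 for leukocyte genes in ASC against QSC. For LncMyod siRNA against control siRNA, the immediate early (0.0132), myogenic (0.743) and endothelial (0.0333) lists reversed direction. The correlation across genes between the LncMyod siRNA change and the culture change was −0.413.

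With equal list lengths control siRNA-specific regions numbered 10131 and ASC-specific regions 7563, and LncMyod siRNA-specific regions 1182, with the ratio reversed to 0.776. Changed genes numbered 2979 for control siRNA against ASC (769 shared) and 23 for LncMyod siRNA (0 shared). Adjusted p was 0.0520 for quiescence and 0.0520 for leukocyte genes in ASC against QSC, 0.345 for immediate early and 0.345 for leukocyte genes in control siRNA against ASC, and 0.743 for myogenic and 0.0547 for contractile genes under LncMyod siRNA. The correlation across genes was −0.429. With 500 bp bins, ASC-specific regions numbered 8253 against control siRNA (ratio 2.12) and control siRNA-specific regions 3363 against LncMyod siRNA.

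Without scaling, changed genes numbered 1820 (1748 shared), 368 (340 shared) and 38 (6 shared) in the 3 comparisons in order. For control siRNA against ASC, immediate early genes had adjusted p = 0.0987 and myogenic genes 0.0377. With quantile normalization LncMyod siRNA changed 10 genes, and adjusted p was 0.140 for quiescence and 0.0681 for leukocyte genes in ASC against QSC and 0.0549 for immediate early genes in control siRNA against ASC. A pseudocount of 2000 bp gave 10 genes for LncMyod siRNA and adjusted p = 0.0707 for leukocyte genes in ASC against QSC. Peak number gave 200 genes for LncMyod siRNA, and adjusted p = 0.0717 for leukocyte genes in ASC against QSC and 0.0943 for immediate early and 0.162 for leukocyte genes in control siRNA against ASC.

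Gene bodies alone gave 50 genes for LncMyod siRNA and adjusted p = 0.173 for quiescence and 0.0889 for leukocyte genes in ASC against QSC, 0.147 for immediate early genes in control siRNA against ASC and 0.111 for contractile genes under LncMyod siRNA. Gene bodies with 50 kb gave 7086, 1757 and 3 changed genes in the 3 comparisons, and adjusted p = 0.135 for immediate early and 0.427 for leukocyte genes in control siRNA against ASC. A fit on the 4 libraries of a pair gave 1186, 704 and 0 genes (2395 at an unadjusted p under 0.05 for LncMyod siRNA in limma). With an estimated correlation, adjusted p was 0.249 for quiescence and 0.249 for leukocyte genes in ASC against QSC, 0.350 for immediate early, 0.136 for contractile and 0.220 for leukocyte genes in control siRNA against ASC, and 0.131 for myogenic and 0.471 for contractile genes under LncMyod siRNA.

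The replicate number was also fitted as a block. Deviations of same-numbered libraries from their group means correlated at 0.00783 to 0.0964 over the 6 pairs of groups, so the numbers were not taken to pair the libraries. With the block, changed genes numbered 3193, 551 and 0 (2809 at an unadjusted p under 0.05 in limma for the last).

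With 1 library left out, in ASC against QSC, ASC-specific regions ran from 9613 to 17931, QSC-specific regions from 12960 to 18433, their ratio from 0.541 to 1.38 (reversed without ASC replicate 2), and changed genes from 712 to 2997. Adjusted p ran from 0.00603 to 0.104 for quiescence and 0.0151 to 0.240 for leukocyte genes. In control siRNA against ASC, ASC-specific regions ran from 5088 to 10690, the ratio from 1.69 to 4.62 and changed genes from 0 to 707. Adjusted p ran from 0.0128 to 0.0960 for immediate early and 0.0128 to 0.0960 for leukocyte genes, and 0.0242 to 0.651 for fibroadipogenic markers. In LncMyod siRNA against control siRNA, LncMyod siRNA-specific regions ran from 4654 to 15692, control siRNA-specific regions from 2587 to 11970, and the ratio from 0.751 to 6.07 (0.835 without control siRNA replicate 1). Changed genes ran from 0 to 343, and adjusted p from 0.00136 to 0.0621 for myogenic and 2.18e-04 to 0.333 for contractile genes. The correlation across genes ran from −0.409 to −0.230.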

Other observations

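The tests of unequal list lengths, of the length of the peak lists, also for the contractile and myogenic lists, of peaks near the calling threshold and of peaks missed in LncMyod siRNA replicate 2 were chosen after the result was seen, as were the gene families, the regions grouped by presence, the oligoadenylate synthetase loci, the chromosome X share and the 20000 strongest peaks.

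Regions grouped by their presence in both libraries of a group, or in neither, differed in how often the LncMyod siRNA libraries held them. Of 12339 regions found in control siRNA and in neither QSC nor ASC, 54.7% were held by both LncMyod siRNA libraries and 9.52% by neither. Of 2704 regions held by QSC and control siRNA but not ASC, 62.5% were held by both, and of 5358 held by ASC and control siRNA but not QSC, 85.0% were. The 8175 regions of QSC that neither ASC nor control siRNA held were absent from both LncMyod siRNA libraries in 89.6% of cases, and 36761 regions common to QSC, ASC and control siRNA were held by both LncMyod siRNA libraries in 96.0%. No p is given for these shares, since neighbouring regions of 8 libraries are not replicates. The groups of regions also differ in how many libraries they were chosen to be present in. The shares therefore do not by themselves show an effect of the knockdown.

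Of 123 gene families formed by a shared symbol stem, 3 were higher in ASC than in QSC by camera at the preset correlation, and none passed in the other comparisons. With an estimated correlation all 3 calls were lost (adjusted p = 0.998 for each). The keratin genes (Krt) had a median log2 change of 0.82, positive in 42 of 48 genes lying in 4 windows of 1 Mb (adjusted p = 8.28e-05). The serine protease genes (Prss) had 0.60, positive in 29 of 33 genes in 16 windows (adjusted p = 0.0273), and the Myo genes 0.32, positive in 24 of 25 genes in 24 windows (adjusted p = 0.0352). The Myo stem leaves out the myosin genes named Myh and Myl, among them those of the sarcomere. The medians of the 3 families stayed positive without scaling (0.75, 0.54 and 0.26) and with quantile normalization (0.62, 0.46 and 0.23), the Myo call being lost without scaling (adjusted p = 0.0636). Neighbouring genes can share peaks.

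In the oligoadenylate synthetase cluster on chromosome 5, neighbours of Oas1f were also listed at 0 in control siRNA. Oas1h had 421.1 and 579.2 scaled bp in the LncMyod siRNA libraries (adjusted p = 0.139 by limma) and Oas1d 230.5 and 1516 scaled bp (adjusted p = 0.395), both at 0 in all QSC, ASC and control siRNA libraries. Oas2 had 910.2 and 1539 scaled bp in LncMyod siRNA and 212.2 and 217.4 in control siRNA (adjusted p = 0.129). Chromosome X held 1.94% and 1.84% of the peaks in QSC, 1.69% and 1.45% in ASC, 1.73% and 1.69% in control siRNA and 1.51% and 1.20% in LncMyod siRNA. With equal list lengths, ASC replicate 2 (1.45%) and LncMyod siRNA replicate 2 (1.5%) lay below the other 6 libraries, at 1.81% to 1.99%. The list of ASC replicate 2 was the shortest, so that setting left it unchanged. With the stricter threshold ASC replicate 2 (1.886%) lay above both control siRNA libraries (1.831% and 1.789%). LncMyod siRNA replicate 2 (1.635%) was then still the lowest.

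LncMyod siRNA replicate 1 shared more covered sequence with the control siRNA libraries than with LncMyod siRNA replicate 2, by 0.104 on the Jaccard index. Unequal list lengths were argued against as the whole cause by a difference of 0.0686 with equal lengths. Weak peaks of a noisier library were argued against by 0.0403 among the 20000 strongest peaks of each library, both values lying above the bound of 0.02, while replicate 2 was then closer to replicate 1 (0.726) than to the controls (0.721 and 0.716). The difference shrank at both settings, so part of it may come from either. No biological explanation was tested, and a difference in knockdown between the libraries stays open.

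More regions were specific to LncMyod siRNA than to control siRNA with all peaks, and fewer with the stricter threshold. With equal list lengths the LncMyod siRNA-specific count minus the control siRNA-specific count was −342, so the length of the peak lists may be the source of the excess. Shortening removes the peaks with the lowest −log10 p, so this setting does not tell list length from weak peaks. A −log10 q of at least 5 in both replicates was reached by 9 of 3115 LncMyod siRNA-specific regions (0.289%). Of the 2012 control siRNA-specific regions, 136 (6.76%) reached it. The excess therefore lay among regions below that value in a replicate, which were most of the regions on both sides. The difference of 6.47 points could not have reached the bound of 10, so this test does not tell peaks near the calling threshold from other sources. An effect of the knockdown on the number of accessible regions stays open.

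As lists, contractile and myogenic loci had less covered length in LncMyod siRNA than in control siRNA with all peaks, and both calls were lost with an estimated correlation (adjusted p = 0.471 and 0.131) and with equal list lengths (adjusted p = 0.0547 and 0.743). Scaling and general accessibility of the loci were argued against with all peaks, since the contractile median (−0.22, against −0.06 for random lists matched on covered length) lay at percentile 0 of 10000 lists and the myogenic median (−0.16 against −0.07) at percentile 0.79. With equal list lengths the contractile median (−0.10) stayed at percentile 0, so unequal lengths of the peak lists may not be the whole cause. Random lists carry neither the correlation among list genes nor the spread between libraries. A low percentile therefore does not tell an effect of the knockdown from variation between libraries. The myogenic median with equal list lengths (−0.03) lay at percentile 24.4, so unequal lengths may be the source of the myogenic pattern. That median turned to 0.04 with the stricter threshold, which leaves the lists unequal and so does not bear on their lengths. Peaks missed in LncMyod siRNA replicate 2 cannot be told apart for the contractile list, because with replicate 1 alone its median of −0.16 lay at percentile 2.58, next to the bound of 2.5. A candidate explanation for the contractile list, a hypothesis found and tested on the same libraries, is loss of accessibility gained in culture. Across its 49 genes, which are not independent replicates, the changes with the control libraries split correlated at r = −0.43 and −0.51 (permutation p = 0.00204 and 0.00018, two-sided), against −0.12 and −0.13 over all genes. These p-values test against no correlation and not against the values over all genes. Peaks missed in LncMyod siRNA replicate 2 could also give a negative correlation, so the correlation does not tell this explanation from that one.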
